A study of Mus musculus with 18 samples.

How the data were processed

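RNA was measured in cortical neurons of WT and Fmr1 KO mice. Per the labels' protocols, cells were grown in Neurobasal medium with B27, treated at 7 days in culture for 24 h, and lysed for RNA purification with RNeasy columns. Libraries were made with a TruSeq RNA kit and sequenced as 75 bp single reads on a NextSeq500. Per the submitters' processing notes, reads were aligned with TopHat2 2.1.0 to the mm9 mouse genome, handled with SAMtools 0.1.19 and counted with HTSeq 0.6.1, and DESeq2 and DESeq were used without a version being given. The library strandedness and the counting mode are not given in the sources used here, so values of overlapping or antisense genes are uncertain.

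The deposited count table holds raw read counts per Ensembl gene for 12 of the 18 samples in the labels. The 6 samples treated with the CDK7 inhibitor THZ1 were not analysed here, so the fit held 4 groups of 3 rather than 6, with 8 residual degrees of freedom. The same table holds 92 ERCC spike-in sequences, of which 86 were detected, and these were left out of the library sizes. The amount added per sample is not given in the sources used here. The authors' DESeq2 table of KO against WT gives, for 23866 genes, the mean signal (baseMean, a normalised count), the log2 fold change with its standard error, the Wald score and the p-value, raw and adjusted. The deposited log2 values are KO over WT, as the negative value of Fmr1 shows. The authors' model is not stated. Its mean signal equals the size-factor scaled mean of the 6 DMSO libraries, with a largest relative gap of 2.6e-09. That table was compared with the calls and log2 changes obtained here and was not used in any test.

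Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr at a minimum count of 10 by group, which left 15433 of 37310 and dropped 21877, and libraries were scaled with TMM. A negative binomial model with 1 mean per group was fitted to the 12 libraries (biological coefficient of variation 6.69%, prior degrees of freedom 6.21), and quasi-likelihood F tests were run for 5 comparisons: KO against WT in DMSO and in JQ1, JQ1 against DMSO in WT and in KO, and the difference between these responses. P-values were adjusted with the Benjamini-Hochberg method over the 15433 genes, and an adjusted p under 0.05 is a call. Standard errors of log2 changes come from the quasi-likelihood statistic. CPM values use TMM-scaled library sizes. Library totals ran from 21643592 to 134110850 gene counts. Replicates of a group differed by more than counting error (chi-square per degree of freedom 4.94 to 41.4), so the spread between libraries, and not their depth alone, limits the values.

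The tests, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined. The rule took Fmr1, then the 10 rising and 10 falling genes of largest absolute log2 change among called genes with a mean of at least 3 CPM in the higher group and no overlap between the libraries of the groups. It was applied to KO against WT in DMSO and to JQ1 in WT, each gene of the latter being quoted with its KO value, and with 3 genes per direction to KO against WT in JQ1. Unnamed gene models were passed over, and not every gene that the rule takes is named in the text. From each described list up to 4 members of smallest adjusted p were named, and a few more where a count of 5 or fewer, or a contrast with the list's name, asked for it.

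The 31 gene lists hold cell type markers, synaptic, activity-regulated, chromatin, transcription, stress and metabolic genes. They were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, two-sided, adjusted over the 31 lists within a comparison. The same test with the correlation estimated per list, and fry, which does not compare a list with other genes, served as alternatives. Another 7 lists were written after the leading genes had been seen and are reported in the closing section alone. Medians of lists are given with bootstrap standard errors where they are compared. These resample the genes of a list as if independent, so they do not measure the spread between libraries.

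Whether replicate numbers pair the libraries was checked from correlations of deviations from the group means. They ran from 0.21 to 0.29 for pairs of the same number in JQ1 against DMSO in KO, from 0.094 to 0.16 in WT, from -0.18 to 0.011 between genotypes in DMSO and from -0.016 to 0.12 in JQ1. In JQ1 against DMSO, 3 numbers correlated best with their own in WT and 3 in KO. Between genotypes 0 did in DMSO and 2 in JQ1. No block was used in the reported fit, and fits with the replicate number or the culture as a block are given as alternatives. The fit was tested on simulated data in which 200 of 15433 genes were changed. For a 2-fold change it recovered 87.9% of genes in 3 of the comparisons, 78.8% for KO against WT in JQ1 and 71.2% for the difference of responses. For a 25% change it recovered from 39.7% to 44.1% in the first 4 comparisons and 10.3% for the difference of responses. From 4.12% to 7.86% of calls were false. Alternatives were other scalings (median of ratios, total counts, summed ERCC counts), other filters, DESeq2 1.42.0, fits of the compared groups alone, blocks, and leaving out each library in turn. Scaling to ERCC counts, the culture block and leaving out both KO replicate 3 libraries were added after seeing the data. Gene names came from the deposited count table, and the gene lists were matched to these names. Neighbours and lengths came from a GENCODE annotation of the GRCm38 assembly, in which 14882 of the 15433 tested genes were found by Ensembl identifier (96.4%).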

Results

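Transcript levels were measured by RNA sequencing in cultured mouse cortical neurons, either wild type (WT) or knockout (KO) for Fmr1, the gene of the RNA-binding protein FMRP. After 7 days in culture the neurons had received vehicle (DMSO) or JQ1, which blocks the acetyl-lysine binding pockets of the BET bromodomain proteins, for 24 h. Read counts were analysed for 12 libraries in 4 groups of 3: WT in DMSO, KO in DMSO, WT in JQ1 and KO in JQ1. Gene counts per library, in replicate order, were 33118140, 36859618 and 35006469 for WT in DMSO and 53564043, 64000804 and 53174615 for KO in DMSO. They were 53237428, 134110850 and 21643592 for WT in JQ1 and 38770458, 78331837 and 34625688 for KO in JQ1. Of 37310 genes, 15433 had enough counts to be tested. The first principal component held 67.8% of the variance and parted JQ1 from DMSO, and the second held 9.63% and parted the genotypes. WT_JQ1 replicate 3, the shallowest library, lay apart on the third, at -30.3 against -7.45 to 11.8 for the others. The labels number the libraries of each group n1 to n3 but do not say whether these were separate cultures or animals, so the p-values measure the spread between these samples. All log2 changes below are relative to the middle of all genes, because scaling to spike-in RNA instead moved the median of all genes by -0.82 (KO over WT in DMSO), -0.12 (KO over WT in JQ1), -0.63 (JQ1 over DMSO in WT) and 0.067 (JQ1 over DMSO in KO) on the log2 scale.

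The comparison of KO with WT neurons in DMSO asks which transcripts differ when FMRP is missing. Fmr1 itself (ENSMUSG00000000838) fell from 120.9 ± 2.89 CPM (read counts scaled to library size) in WT to 24.4 ± 4.40 in KO (mean ± SD, n = 3 each), a log2 change of -2.31 (SE 0.113, adjusted p = 9.2e-08). Mid1 (ENSMUSG00000035299), an X-linked gene of a microtubule-bound ubiquitin ligase, fell further, from 72.5 ± 20.1 to 8.44 ± 0.996 CPM, with a log2 change of -3.10 (SE 0.184, adjusted p = 6.54e-07). Vip, the neuropeptide of a class of cortical interneurons, rose from 0.989 ± 0.353 to 3.50 ± 0.869 CPM, a log2 change of 1.82 (SE 0.302, adjusted p = 0.00265). Sox5 and Tle4, transcriptional regulators of deep-layer projection neurons, fell by 1.02 (SE 0.0762, adjusted p = 9.17e-06) and 0.98 (SE 0.109, adjusted p = 0.000183) on the log2 scale. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2311 of the 15433 genes passed an adjusted p of 0.05, 1113 higher and 1198 lower in KO, most by small amounts (median absolute log2 change 0.268). Of these, 21 rose and 40 fell by more than 2-fold.

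The other leading genes that fell in KO were Nhlh2 (log2 change -1.59, SE 0.169), a transcription factor of Cajal-Retzius and neuroendocrine cells, Dmrt2 (-1.50, SE 0.207), a DM-domain transcription factor, Dcn (-1.36, SE 0.197), the matrix proteoglycan decorin, and Trp73 (-1.25, SE 0.193), a p53 relative found in Cajal-Retzius cells. Nxph3 (-1.16, SE 0.127), a neurexin ligand of deep-layer neurons, and the cadherin Cdh7 (-0.94, SE 0.0958) also fell. Their adjusted p-values ran from 0.000136 for Cdh7 to 0.00175 for Trp73. Among genes that rose were Hapln1 (1.24, SE 0.268), which links hyaluronan to the proteoglycans of perineuronal nets, the vesicle protein gene Sv2c (0.95, SE 0.176), the acid-sensing channel gene Accn4 (0.94, SE 0.17), the activity-induced transcription factor gene Egr1 (0.92, SE 0.137) and Prox1 (0.88, SE 0.13), a homeobox gene of caudally derived interneurons. The scavenger receptor gene Marco (1.11, SE 0.326), the muscle genes Myh8 (0.92, SE 0.196) and Neb (0.84, SE 0.202), and the matrix gene Dpt (0.81, SE 0.151) also rose. Of these 9 genes, Prox1 had the smallest adjusted p (0.00138) and Marco the largest (0.0361). All of the 9 but Hapln1 and Egr1 had means under 10 CPM in both DMSO groups. Nhlh2, Dmrt2, Trp73 and Cdh7, which fell, were also under 10 CPM in both. Marco lost its call without WT_DMSO replicate 1, 2 or 3 or KO_DMSO replicate 1 (adjusted p = 0.0805, 0.124, 0.0766 and 0.175) and in a fit of the 6 DMSO libraries alone (0.0502). Neb lost its call without WT_DMSO replicate 1 or 2 or KO_DMSO replicate 1 or 2 (adjusted p = 0.0629, 0.07, 0.0586 and 0.0565).

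**Figure D1:**
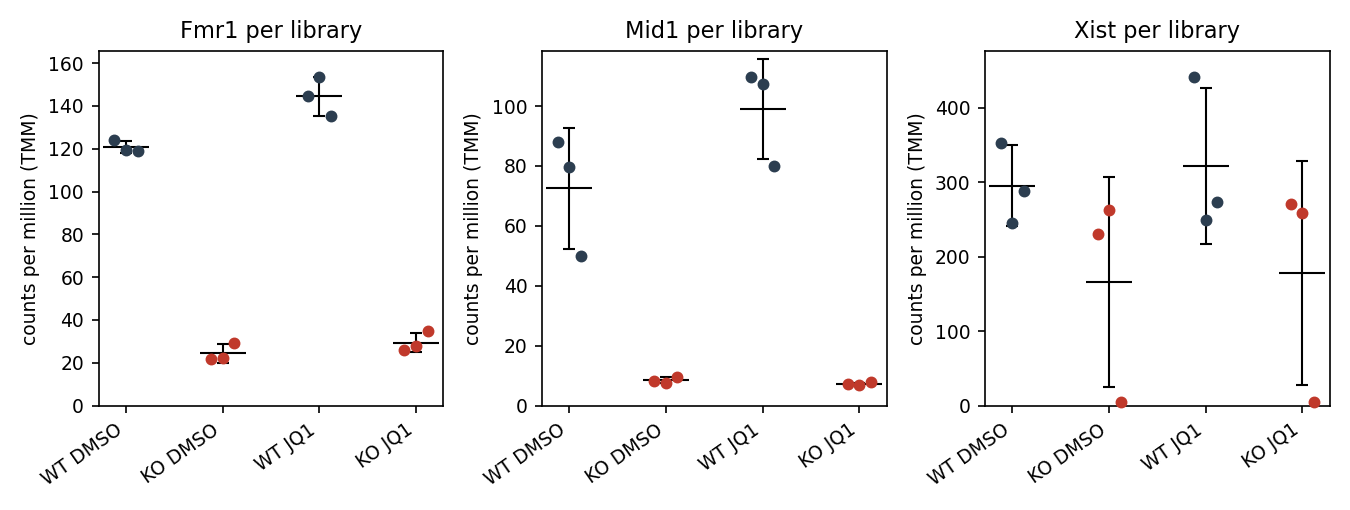
Each point is 1 library's level of Fmr1, Mid1 or Xist in TMM-scaled CPM, and the black lines mark the mean of the 3 libraries of a group with its SD. Fmr1 and Mid1 are lower in every KO library than in every WT library, and Xist is at 4.29 and 4.34 CPM in the replicate 3 KO libraries of DMSO and JQ1 and at 230.5 CPM or more in the other 10 libraries.

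Among the 31 gene lists fixed beforehand, inhibitory neuron markers rose in KO in DMSO, with a median log2 change of 0.39. Of the 18 measured markers, 11 rose and 0 fell (14 and 0 adjusted over the list alone). Among them were Vip and the interneuron transcription factor genes Sp9 (0.48) and Dlx5 (0.67). The set test camera gave an adjusted p = 1.55e-08 for this list, and adjusted p = 0.54 with an estimated correlation. Presynaptic genes rose as well (median 0.21), with 13 of 29 higher and 0 lower (15 and 0 adjusted over the list alone). These included the release machinery gene Vamp2 (0.32) and the vesicle protein genes Syp (0.33) and Sv2a (0.31). That list had an adjusted p = 5.96e-08, and adjusted p = 0.54 with an estimated correlation. Messenger RNAs bound by FMRP had a median of 0.22, and 16 of 53 rose while 1, the glutamate receptor gene Grm5 (-0.22), fell (22 and 1 adjusted over the list alone). The synaptic adhesion genes Nlgn2 (0.34) and Nrxn2 (0.25), the scaffold gene Dlg4 (0.26) and the mTOR regulator Tsc2 (0.25) were among those that rose, and the list's adjusted p = 3.87e-11 became adjusted p = 0.54 with an estimated correlation. Without both KO replicate 3 libraries, 28 of the 53 rose and 0 fell.

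Postsynaptic glutamatergic genes were split, with 8 of 32 higher and 4 lower (13 and 5 adjusted over the list alone). Grin1 (0.44) and Gria1 (0.33) rose and the kainate receptor gene Grik2 (-0.38) fell. The list median was 0.13 (adjusted p = 0.00177, and adjusted p = 0.54 with an estimated correlation). Voltage-gated channel genes had 7 of 29 higher and 0 lower (7 and 0 adjusted over the list alone), led by the sodium channel subunit gene Scn2b (0.36) and including Cacna1g (0.28). Their median was 0.14 (adjusted p = 6.33e-04, and adjusted p = 0.54 with an estimated correlation). Of 21 cholesterol synthesis genes, 7 rose and 0 fell (8 and 1 adjusted over the list alone), led by the mevalonate pathway genes Mvd (0.32) and Mvk (0.22) and by Dhcr7 (0.26). The list had an adjusted p = 6.92e-04, and adjusted p = 0.54 with an estimated correlation. Of 79 ribosomal protein genes, 12 rose and 2 fell (19 and 3 adjusted over the list alone), Rpl18 (0.40) foremost, around a median of 0.057 (adjusted p = 0.00177, and adjusted p = 0.771 with an estimated correlation). Of 80 nuclear oxidative phosphorylation genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone), such as Ndufa9 (0.21), with an adjusted p = 0.0109, and adjusted p = 0.771 with an estimated correlation. Chromatin regulators had 11 of 52 higher and 4 lower (12 and 6 adjusted over the list alone). Mll2 (0.41) rose, and the histone demethylase gene Kdm6a (-0.47) and the methyltransferase gene Ezh2 (-0.41) fell. That list's adjusted p = 0.0112 became adjusted p = 0.771 with an estimated correlation. Without both KO replicate 3 libraries, 17 chromatin regulators rose and 4 fell, and 12 postsynaptic genes rose and 2 fell.

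Progenitor and proliferation markers fell in KO in DMSO (median -0.35), with 6 of 20 lower and 0 higher (12 and 0 adjusted over the list alone). These included the mitotic genes Cdk1 (-0.47), Bub1 (-0.54) and Ccnb1 (-0.51) and the Notch target Hes5 (-0.54). The list's adjusted p = 8.74e-05 became adjusted p = 0.704 with an estimated correlation. Without both KO replicate 3 libraries, 11 of these markers fell and 1 rose. Astrocyte markers had a median of -0.25, with 2 of 15 lower and 0 higher (2 and 0 adjusted over the list alone), the receptor gene Fgfr3 (-0.62) and the gap junction gene Gja1 (-0.60), and an adjusted p = 0.00338, and adjusted p = 0.741 with an estimated correlation. Excitatory neuron markers went both ways (5 of 16 higher, 3 lower; 5 and 5 adjusted over the list alone) and the list did not pass (adjusted p = 0.954). The deep-layer genes Fezf2 (-0.91), Bcl11b (-0.49) and Tbr1 (-0.44) fell and the upper-layer gene Cux2 (0.32) rose.

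**Figure D2:**
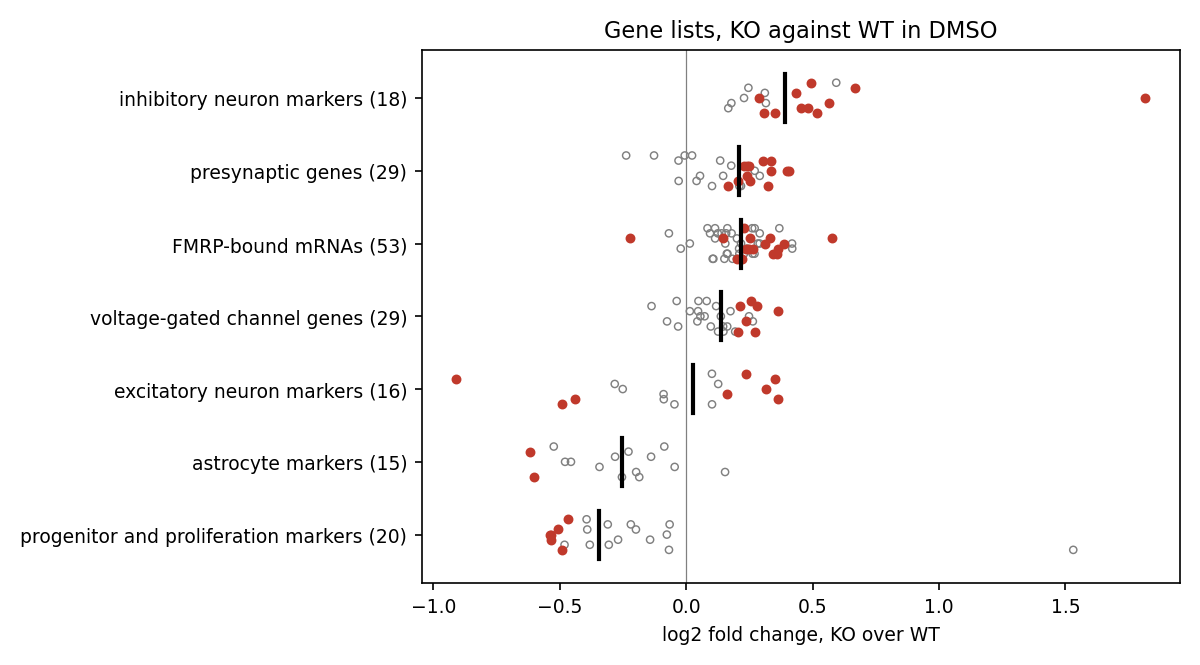
Each point is 1 measured gene of 7 lists (number of genes in brackets) at its log2 change of KO over WT in DMSO, red where it passed an adjusted p of 0.05 and open where not, and the black bar is the list's median. Inhibitory markers (median 0.39), presynaptic genes (0.21) and FMRP-bound mRNAs (0.22) lie mostly above 0, and astrocyte (-0.25) and progenitor markers (-0.35) mostly below, with Eomes (1.53, adjusted p = 0.216) the open point far to the right.

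The KO replicate 3 libraries stood apart in the sex-linked genes: Xist, the RNA that silences an X chromosome in female cells, was at 4.29 CPM in DMSO and 4.34 in JQ1, and the Y-linked Ddx3y at 54.55 and 76.19 CPM, against 230.5 CPM or more and 46.11 CPM or less in the other 10 libraries. KO_DMSO replicate 3 also differed from its group over genes generally, with a chi-square per degree of freedom of 40.7 and 41.4 against replicates 1 and 2, which differed from each other by 7.93. In KO_JQ1 the values were 24.2 and 16.6, against 16.8. Without both of these libraries, 3198 genes passed between KO and WT in DMSO, and the median log2 changes of inhibitory markers (0.41), FMRP-bound mRNAs (0.27), presynaptic genes (0.27), progenitor markers (-0.45) and astrocyte markers (-0.36) kept their directions. Autism risk genes, which did not pass in all libraries (adjusted p = 0.107), passed without them (adjusted p = 0.00461, and adjusted p = 0.646 with an estimated correlation). Leaving out WT_DMSO replicate 1, 2 or 3 or KO_DMSO replicate 1 or 2 took the count to 1218, 1155, 1243, 805 and 1195, and scaling to the spike-in RNA gave 4 genes higher and 11990 lower. In 5803 genes (37.6%) the 3 KO libraries did not overlap the 3 WT libraries in DMSO, where chance gives 10%.

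The same genotypes were compared in JQ1. Mid1 fell from 99.02 ± 16.6 CPM in WT to 7.26 ± 0.402 in KO (n = 3 each; log2 change -3.79, SE 0.192, adjusted p = 7.65e-08), and Fmr1 from 144.5 ± 9.19 to 29.4 ± 4.59 CPM (-2.30, SE 0.113, adjusted p = 7.65e-08). Nhlh2 fell as it had in DMSO (-1.47, SE 0.182, adjusted p = 0.000826). Hapln1 (1.53, SE 0.264, adjusted p = 0.00436), Sv2c (1.15, SE 0.178, adjusted p = 0.00274) and the activity-induced transcription factor gene Npas4 (1.06, SE 0.248, adjusted p = 0.0182) rose. Npas4 was 0.61 in DMSO without passing (adjusted p = 0.109), and its call in JQ1 was lost without WT_JQ1 replicate 1 or 2 or KO_JQ1 replicate 1 (adjusted p = 0.0642, 0.088 and 0.0706). In all, 1385 genes passed, 748 higher and 637 lower in KO, of which 25 and 45 differed by more than 2-fold.

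Inhibitory neuron markers rose in KO in JQ1 too (median 0.33; 5 of 18 higher and 0 lower; 12 and 0 adjusted over the list alone), with Vip (2.22) and Calb2 (0.71) among them. Their adjusted p = 1.16e-07 became adjusted p = 0.677 with an estimated correlation. Presynaptic genes (median 0.12) had 10 of 29 higher and 0 lower (10 and 0 adjusted over the list alone), including Vamp2 (0.33), with an adjusted p = 3.42e-05, and adjusted p = 0.612 with an estimated correlation. Of FMRP-bound mRNAs 5 of 53 rose and 0 fell (6 and 0 adjusted over the list alone), among them Camk2a (0.32) and Nlgn2 (0.23), with an adjusted p = 3.19e-04, and adjusted p = 0.677 with an estimated correlation. Cholesterol synthesis genes (median 0.13) had 4 of 21 higher and 0 lower (6 and 0 adjusted over the list alone), with Mvd (0.28) and Dhcr7 (0.23) foremost (adjusted p = 1.94e-05, and adjusted p = 0.562 with an estimated correlation). Progenitor markers had 4 of 20 lower and 0 higher (14 and 1 adjusted over the list alone), including Vim (-0.41) and Mki67 (-0.52), with an adjusted p = 7.84e-07, and adjusted p = 0.677 with an estimated correlation. Fgfr3 (-0.67) was the 1 of 15 astrocyte markers that fell (1 adjusted over the list alone; list adjusted p = 0.016, and adjusted p = 0.677 with an estimated correlation). Voltage-gated channel genes had 4 of 29 higher, including Scn2b (0.30), and 1 lower, Scn3a (-0.18) (5 and 1 adjusted over the list alone; adjusted p = 0.016, and adjusted p = 0.677 with an estimated correlation). Histone cluster genes had 3 of 29 higher and 0 lower (4 and 0 adjusted over the list alone), namely Hist1h4i (0.39), Hist1h1c (0.26) and Hist1h2ad (adjusted p = 0.0389), with an adjusted p = 0.016, and adjusted p = 0.416 with an estimated correlation. Of 80 oxidative phosphorylation genes 3 rose, among them Ndufa9 (0.19) and Cox6b1 (0.29), and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.01, and adjusted p = 0.868 with an estimated correlation). Of 36 proteasome genes Psmd8 (0.19) alone rose (1 and 0 adjusted over the list alone; adjusted p = 0.016, and adjusted p = 0.677 with an estimated correlation). Several counts rose without the KO replicate 3 libraries: 14 FMRP-bound mRNAs and 8 oxidative phosphorylation genes were higher and 0 lower, 12 progenitor markers were lower and 1 higher, and 3 astrocyte markers were lower. The proteasome list did not pass without these libraries (adjusted p = 0.156, 4 higher and 1 lower). Postsynaptic genes passed without them (adjusted p = 0.0107, and adjusted p = 0.69 with an estimated correlation) but not in all libraries (adjusted p = 0.0513).

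The count in JQ1 depended on the libraries. It was 2086 without KO_JQ1 replicate 3, and 567, 537, 615 and 810 without WT_JQ1 replicate 1, WT_JQ1 replicate 2, KO_JQ1 replicate 1 and KO_JQ1 replicate 2. It was 2497 without both KO replicate 3 libraries, 600 from the 6 JQ1 libraries alone and 23 under spike-in scaling, 5 higher and 18 lower. In 4162 genes (27%) the 3 KO libraries in JQ1 did not overlap the 3 WT libraries, where chance gives 10%.

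The response to JQ1 was compared with DMSO within each genotype, to ask which transcripts depend on BET proteins and whether the response needs FMRP. Histone cluster genes rose about 4-fold in both genotypes, and Hexim1, an inhibitor of the elongation kinase P-TEFb, rose from 29.3 ± 0.54 to 96.7 ± 5.18 CPM in WT (n = 3 each; log2 change 1.72, SE 0.0501, adjusted p = 7.03e-11). In KO Hexim1 rose by 1.64 (SE 0.049, adjusted p = 7.97e-11). Aldh1a3, a retinoic acid synthesis enzyme gene, fell from 23.5 ± 2.16 to 1.53 ± 0.234 CPM in WT (-3.87, SE 0.226, adjusted p = 1.41e-08) and by 3.57 on the log2 scale in KO (SE 0.21, adjusted p = 1.29e-08). In WT, 8507 genes passed, 3990 higher and 4517 lower in JQ1, and in KO 8817 did, 4279 higher and 4538 lower. More genes fell than rose by over 2-fold, 1599 against 147 in WT and 1583 against 137 in KO.

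The other leading genes that rose in WT, with the KO value in brackets, were Hist1h4i 3.45 (3.20), Hist2h2bb 3.43 (3.33) and Hist1h1c 2.16 (2.16), all histone genes, as is Hist1h2bc, which rose 4.01-fold (3.97-fold). Akap13 2.21 (2.25), a kinase anchor gene, Arid5a 1.87 (1.82), an RNA-binding protein gene, the mitochondrial protein gene Chchd7 1.82 (1.83), the thioredoxin inhibitor gene Txnip 1.79 (1.92) and the imprinted retroelement-derived Peg10 1.78 (1.74) followed. Leading genes that fell included Rlbp1 -3.81 (-3.88), a retinaldehyde carrier of glia, Trhr -3.55 (-3.97), a neuropeptide receptor gene, and Scel -3.44 (-2.49), a cornified envelope gene. After them came the small heat shock protein gene Cryab -3.15 (-2.99), Sidt1 -3.09 (-2.89), the keratin gene Krt77 -3.06 (-2.83), the glial glutamate carrier gene Slc25a18 -3.03 (-3.16) and Otof -2.85 (-3.03), a calcium sensor of exocytosis. The adjusted p-values of these genes were at most 7.82e-08 in WT (Peg10) and 2.47e-07 in KO (Scel).

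Of 29 measured histone cluster genes, 26 rose in WT and 25 in KO and 0 fell in either (27 and 25 adjusted over the list alone), with median folds of 4.01 and 4.02. This list kept its call with an estimated correlation in both genotypes (adjusted p = 0.00159 and 0.00151; 1.76e-11 and 1.45e-11 with the preset). Several of these genes are nearly identical copies, and how shared reads were counted is not given in the sources used here, so values of single histone genes are uncertain. BET proteins and P-TEFb regulators had 16 of 21 higher and 4 lower in WT (16 and 4 adjusted over the list alone), with Brd2 (0.63) and the 7SK capping enzyme gene Mepce (0.60) higher and Hexim2 (-1.37) lower. In KO 14 rose and 3 fell (15 and 4 adjusted over the list alone), and the list had adjusted p = 8.89e-04 in WT and 0.00222 in KO. These became adjusted p = 0.0752 and 0.0884 with an estimated correlation. Ribosomal protein genes rose by a small amount, 61 of 79 in WT with 0 lower (66 and 1 adjusted over the list alone) and 46 in KO with 2 lower (46 and 2 adjusted over the list alone). Rps2 (0.64 in WT, 0.55 in KO) and Rps20 (0.57, 0.53) were foremost. Their adjusted p = 7.21e-11 in WT and 4.29e-06 in KO became adjusted p = 0.495 and 0.691 with an estimated correlation. Chromatin regulators had 26 of 52 higher and 4 lower in WT and 22 and 5 in KO (the same numbers adjusted over the list alone). Suz12 (0.60, 0.62) and Dnmt1 (0.47, 0.42) rose and Chd3 (-0.86, -1.03) fell. Their adjusted p = 3.91e-04 in WT and 0.0251 in KO became adjusted p = 0.563 and 0.902 with an estimated correlation. Of 40 autism risk genes, 18 rose and 4 fell in WT (18 and 4 adjusted over the list alone), including Tsc2 (0.54) and the beta-catenin gene Ctnnb1 (0.50), which rose (adjusted p = 0.0076, and adjusted p = 0.606 with an estimated correlation). In KO 12 rose and 6 fell, and the list did not pass (adjusted p = 0.122). The list of CDK7, TFIIH and RNA polymerase II genes passed in KO, with 13 of 28 higher and 1 lower (13 and 1 adjusted over the list alone; adjusted p = 0.0229, and adjusted p = 0.306 with an estimated correlation). In WT 12 rose and 3 fell (adjusted p = 0.0729), among them Polr2a (0.63) and Cdk13 (0.46), which rose. For these last 2 lists the difference between genotypes is given by the tests of KO minus WT below.

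**Figure D3:**
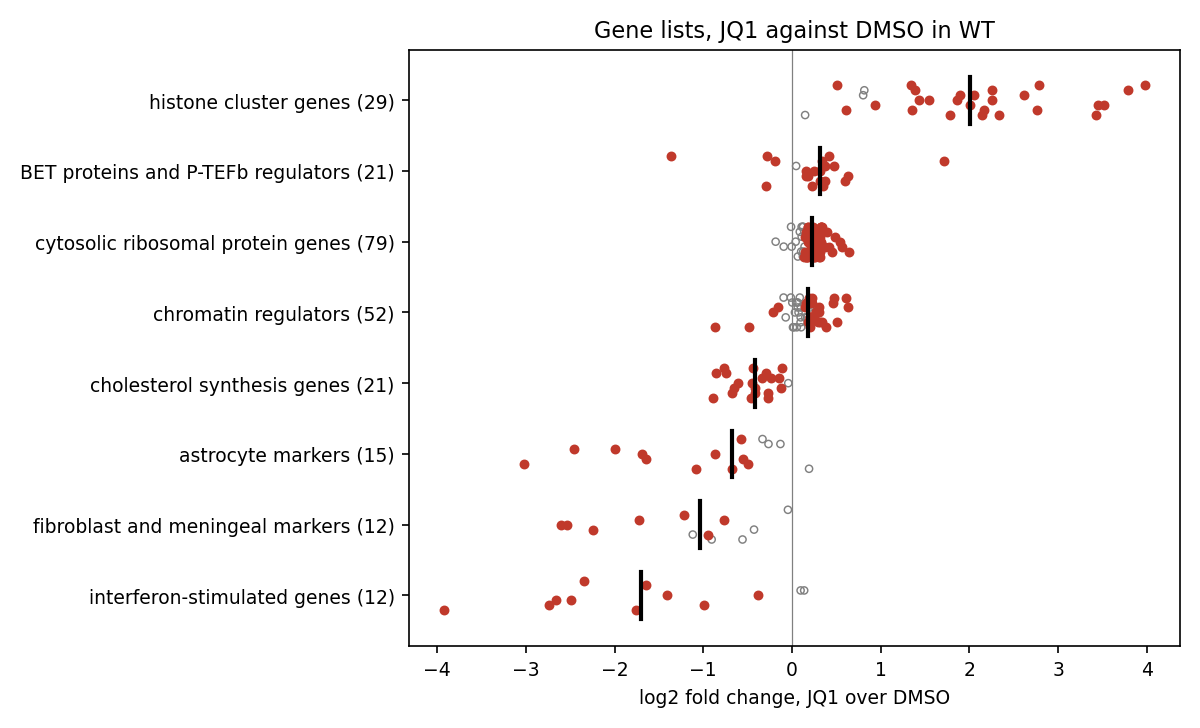
Each point is 1 measured gene of 8 lists (number of genes in brackets) at its log2 change of JQ1 over DMSO in WT, red where it passed an adjusted p of 0.05 and open where not, and the black bar is the list's median. Histone cluster genes lie to the right (median 4.01-fold) and interferon-stimulated genes (median -1.70) to the left.

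Cholesterol synthesis genes fell in JQ1, 20 of 21 in WT and 18 in KO with 0 higher (20 and 18 adjusted over the list alone), with medians of -0.42 and -0.37. Insig1 (-0.66 in WT, -0.69 in KO), Fdps (-0.75, -0.75), Mvd (-0.86, -0.90) and Tm7sf2 (-0.77, -0.75) were among them, and the list's adjusted p = 2.83e-08 and 1.73e-07 became adjusted p = 0.114 and 0.103 with an estimated correlation. Markers of 3 kinds of non-neuronal cells fell, those of astrocytes, fibroblasts and microglia, while oligodendrocyte lineage markers (adjusted p = 0.445 in WT and 0.356 in KO) and endothelial and pericyte markers (0.25 and 0.381) did not pass. Of 15 astrocyte markers, 11 fell in WT and 10 in KO (11 and 10 adjusted over the list alone), among them the water channel gene Aqp4 (-2.46, -2.18), the neurotensin receptor gene Ntsr2 (-1.69, -1.65) and Mlc1 (-1.65, -1.52). Their adjusted p = 7.33e-04 and 0.00183 became adjusted p = 0.563 and 0.641 with an estimated correlation. Of 12 fibroblast and meningeal markers, 7 fell in WT and 8 in KO (7 and 8 adjusted over the list alone), such as Col6a3 (-2.60, -2.69) and Fn1 (-1.22 in WT), with adjusted p = 0.00388 and 0.00222, and adjusted p = 0.134 and 0.103 with an estimated correlation. Of 14 microglia markers, 6 fell in WT and 9 in KO (6 and 9 adjusted over the list alone), such as the receptor gene Cx3cr1 (-1.76, -1.90), with adjusted p = 0.0296 and 0.0151, and adjusted p = 0.606 and 0.641 with an estimated correlation. Interferon-stimulated genes had 10 of 12 lower in both genotypes (10 adjusted over the list alone) and 1 higher in KO, Stat2 (0.24). Ifit2 (-1.41, -1.23), Rsad2 (-2.74, -2.51) and Oasl2 (-3.92, -4.55) were among those that fell. Their adjusted p = 0.00311 and 0.00453 became adjusted p = 0.0752 and 0.0884 with an estimated correlation. Of 5 measured inflammatory genes, 5 fell in WT and 4 in KO (5 in each adjusted over the list alone), including Vcam1 (-1.07, -0.95) and Nfkbia (-0.33, -0.36), with adjusted p = 0.0405 and 0.0483, and adjusted p = 0.218 and 0.244 with an estimated correlation. With total-count scaling the microglia and inflammatory lists did not pass in WT (adjusted p = 0.0695 for each), nor did the chromatin (0.0671) and inflammatory (0.0784) lists in KO. Over all genes, 43.2% of the lowest expression quartile fell in WT and 14.3% of the highest (44.2% and 15.1% in KO). In WT 6.63% and 42.2% of these quartiles rose. The lists that rose or fell in JQ1 were not compared with genes of like expression, so part of their change may go with expression level.

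The WT and KO libraries did not overlap between JQ1 and DMSO in 9656 genes (62.6%) and 9373 genes (60.7%), where chance gives 10%. Under spike-in scaling the KO comparison called 1520 genes, 206 higher and 1314 lower, and the WT comparison 5854, 40 higher and 5814 lower. With total counts alone the splits were 2738 higher and 5477 lower in WT and 3035 and 5371 in KO.

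The last comparison asks whether the response to JQ1 differed by genotype. The log2 responses in WT and KO correlated over the 15433 genes, which are not independent replicates, with r = 0.936 (jackknife SE 0.026 over libraries) and a slope of 0.931. This value holds for genes that passed the count filter, and without a filter, over 25048 genes, it was 0.44. Of genes that rose, 3519 were called in both genotypes, where 1106 would be shared if the calls were independent, and of genes that fell 3973, against 1328. Of 7493 genes called in both, 1 went opposite ways: Snx7, a sorting nexin gene singled out after its values were seen, at -0.32 in WT (adjusted p = 0.0116) and 0.24 in KO (adjusted p = 0.0388), with an adjusted p of 1 for the difference. edgeR called 0 genes for the difference between the genotypes' responses, with 355 genes at an unadjusted p under 0.05, and DESeq2 called 0 with 235. With the culture as a block edgeR called 0 with 688. The reported fit holds no block, so deviations shared by DMSO and JQ1 libraries of the same number stay in its error. In simulated data the edgeR test without a block recovered 10.3% of genes with a 25% difference, 59.1% with a 1.5-fold and 71.2% with a 2-fold difference. Differences as small as most genotype changes in DMSO (median absolute log2 change 0.268) were thus mostly not detectable in the fit without a block, at this depth and number of libraries.

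**Figure D4:**
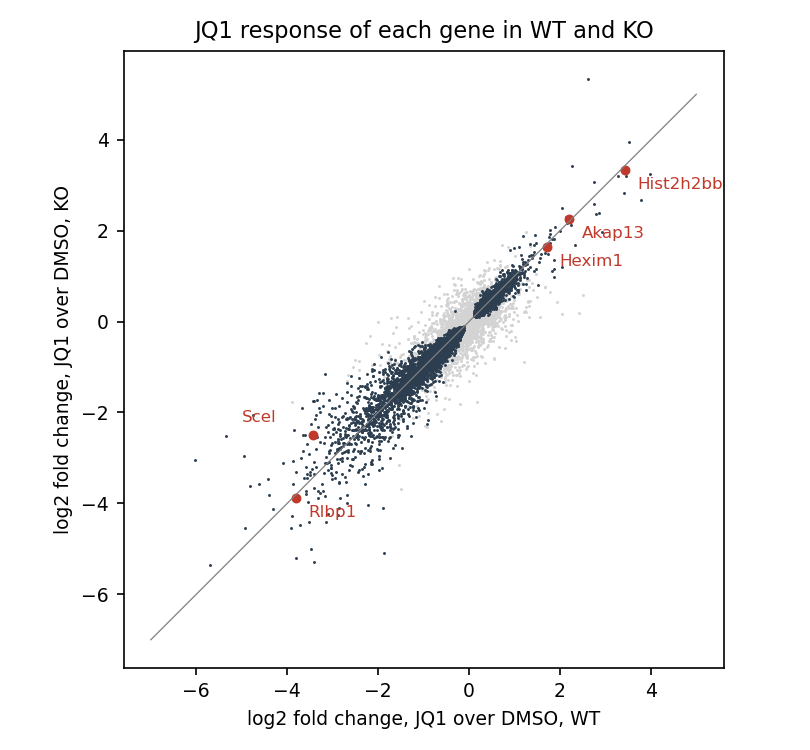
Each point is 1 gene, with its log2 change of JQ1 over DMSO in WT on the horizontal axis and in KO on the vertical axis, dark where it was called in both genotypes and light grey otherwise, with 5 named genes in red and the grey line marking equal changes. The responses correlate with r = 0.936 over 15433 genes, and Scel (-3.44 in WT, -2.49 in KO) lies above the line.

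At the level of lists, 6 were lower in the KO response than in the WT response by small amounts and without a called member. This difference uses the same DMSO libraries as the comparison of KO with WT in DMSO. There, all of these lists but autism risk genes had passed as higher. A deviation that raised a list in KO in DMSO would also lower its KO response, so these results are not independent. Some of these lists also share members, such as Tsc2, which is both an FMRP-bound mRNA and an autism risk gene. With fry each of the 6 lists had adjusted p = 0.936. The largest median differences were those of FMRP-bound mRNAs (-0.11, adjusted p = 9.16e-08) and ribosomal protein genes (-0.065, adjusted p = 2.87e-08), both with adjusted p = 0.727 with an estimated correlation. Autism risk genes differed by -0.053 (adjusted p = 0.00243) and chromatin regulators by -0.042 (adjusted p = 7.69e-05), each with adjusted p = 0.727 with an estimated correlation. Presynaptic (-0.032, adjusted p = 0.0227) and postsynaptic genes (-0.040, adjusted p = 0.0447) also had adjusted p = 0.727 with an estimated correlation. The CDK7, TFIIH and RNA polymerase II list did not differ past the threshold (adjusted p = 0.328).

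The genotype effect was also followed from DMSO into JQ1, 2 comparisons that share no library but were not independent of each other in every respect. Deviations from the group means correlated between DMSO and JQ1 libraries of the same number (0.094 to 0.16 in WT, 0.21 to 0.29 in KO), and both KO replicate 3 libraries had little Xist. Of the 2311 genes called between KO and WT in DMSO, 2280 (98.7%) had the same sign in JQ1, with a slope of 0.77 (jackknife SE 0.19). In 20 simulations a JQ1 effect was included and the genotype effect was equal in both treatments. The slope then averaged 0.725 (0.672 to 0.76) and the same-sign share 96.6% (95.9% to 97.3%), with both ranges below the observed values. Effects of genes picked by significance shrink when measured again, which the simulations include. The simulations held no deviation shared between DMSO and JQ1 libraries of a number, which would raise the observed slope and the overlap of calls. Adjusted over the 2311 genes alone, 1643 passed in JQ1 in the same direction and 1 in the opposite one. This was Kctd12b (-0.56 in DMSO, 0.58 in JQ1), singled out after its values were seen. Of genes higher in KO 540 were called in both treatments, where 54 would be shared if independent, and of genes lower in KO 435, against 49. Under spike-in scaling the slope was 0.234.

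The genotype and JQ1 effects were then set against each other, with the genotype effect averaged over treatments and the JQ1 effect averaged over genotypes. Over genes the correlation was 0.0071. Genes higher in KO (2215) fell with JQ1 in 34.6% of cases, against 35.7% of the 10756 genes with no genotype call (Fisher's exact test, two-sided, p = 0.342). Genes lower in KO (2462) rose with JQ1 in 39.2% of cases, against 31.6% (Fisher's exact test, p = 4.76e-13). Genes higher in KO rose in 34.3% of cases, so part of the excess over 31.6% went with a genotype call in either direction. Fisher's test treats genes as independent, which they are not, and the share of genes that rose also varied with expression, from 6.63% in the lowest to 42.2% in the highest quartile in WT. Fmr1 and Mid1, both lower in KO, rose with JQ1 in WT (0.26, adjusted p = 0.049, and 0.46, adjusted p = 0.0254) and did not pass in KO (0.27, adjusted p = 0.0572, and -0.22, adjusted p = 0.364). The KO minus WT differences of these responses did not pass either (0.0075 for Fmr1 and -0.68 for Mid1, adjusted p = 1 for each).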

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

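The tests of the pan-neuronal-minus-inhibitory difference and of the inhibitory markers in JQ1 were chosen only after the result was seen, and leaving out both KO replicate 3 libraries was likewise chosen after seeing the data.

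Lists stood out where the test of the difference between the genotypes' JQ1 responses passed with the preset correlation: FMRP-bound mRNAs (median log2 difference, KO minus WT, -0.113), ribosomal protein genes (-0.0651), autism risk genes (-0.0527), chromatin regulators (-0.042), postsynaptic genes (-0.0398) and presynaptic genes (-0.0319). With an estimated correlation none of these 6 lists passed (adjusted p = 0.727 for each), and no member was called. The difference uses the same DMSO libraries as the comparison of KO with WT in DMSO, so it is not separate evidence. Spike-in RNA, which the reported tests do not use, made up 0.254% of counts in KO in DMSO, 0.205% in WT in JQ1 and 0.214% in KO in JQ1, all above the 0.139% of WT in DMSO, the control group. The exact permutation test, two-sided, gave p = 0.2, 0.1 and 0.1 for these differences, where 0.1 is the smallest p that 3 against 3 libraries allow. Within KO the share was lower in JQ1 than in DMSO, a difference that was not tested. The KO_DMSO libraries ran from 0.168% to 0.348%.

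Inhibitory neuron markers were higher in KO in DMSO. The values go against deeper KO libraries as the whole cause. The markers were also higher by a median of 0.325 in JQ1, where KO libraries were not the deeper ones. The SE of 0.057 is over genes, not libraries. In camera with an estimated correlation the list had adjusted p = 0.677 in JQ1, so this cause is not excluded. A lower share of glial and dividing cells would raise every neuronal marker alike. The median of pan-neuronal markers lay -0.331 (SE 0.11, over genes) from that of inhibitory markers, past the SD of 0.198 over the 16 pan-neuronal genes. These values go against that share as the whole cause. They do not exclude it, since the pan-neuronal list and this test were written after the leading genes and the result were seen. A larger share of inhibitory neurons of every origin stays open: markers of caudal and medial ganglionic eminence interneurons differed by 0.159 (SE 0.24), within their error. Higher expression per inhibitory neuron, a difference between genotypes, was not tested.

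FMRP-bound mRNAs were higher in KO in DMSO. A transcript length trend is argued against: 0 percent of 10000 random lists matched on length and expression had a median as high as 0.217 (median of the matched lists -0.0043; all 53 genes had a length). The random lists were drawn gene by gene and hold no correlation between genes, so this percent is not a p-value of the list. A larger neuronal share stays open, since the median of pan-neuronal markers lay -0.157 (SE 0.084) from that of the FMRP-bound mRNAs, within 2 standard errors. Loss of FMRP itself, the difference the design names, also stays open, as these data hold no measure of binding.

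Mid1 was lower in KO in both treatments. The KO culture with little Xist is argued against as the cause, because Mid1 was at -3.18 (SE 0.23) without both replicate 3 libraries. DNA carried along with the Fmr1 mutation cannot be told apart from an effect of genotype: 4 of the 20 measured genes nearest to Fmr1 were called (Fisher's exact test, p = 0.53), but Mid1 ranks 542 of 545 by distance from Fmr1 on that chromosome. A strain difference at Mid1 itself cannot be told apart from genotype either, since it runs with the groups. The lowest WT library was 5.21 times the highest KO library. Of the 20 measured genes nearest to Mid1, 4 were called (Fisher's exact test, p = 0.53): 2 unnamed gene models (-1.88 and -2.75), Glra2 (-0.80) and Tmsb4x (-0.16). Those 2 models are the nearest of all, and the next nearest, also unnamed, was at -1.55 without passing in edgeR (adjusted p = 0.142). After it came genes at 0.0406 and -0.039. The count over 20 genes thus does not describe the genes closest to Mid1. A genotype effect on Mid1 stays open as a hypothesis.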

How the results depend on the processing

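The spike-in scaling, the culture block and leaving out both KO replicate 3 libraries were chosen after seeing the data; the other alternatives were fixed before it. The alternatives written for THZ1 were not run, as those samples were not analysed here. Of 1030 values of the 66 gene results taken by the rule under alternatives, 1007 kept direction and call, 22 lost the call and 1 reversed (Dpt, KO over WT in DMSO, -0.041 under spike-in scaling, which moved the median of all genes by -0.82); outside spike-in scaling 952 of 964 kept both and 12 lost the call. Leaving out 1 library at a time gave 805 to 2509 genes for KO against WT in DMSO, 537 to 2086 in JQ1, and a WT to KO correlation of the JQ1 response from 0.905 (without WT_JQ1 replicate 2) to 0.932; fewer libraries are part of the cause. Spike-in scaling gave 11994, 23 and 1520 genes for KO against WT in DMSO, in JQ1 and for JQ1 in KO, and a slope of 0.234 for the genotype effect in JQ1, where the median of all genes shifted by -0.82, -0.12 and 0.067. KO against WT in JQ1 called 600 genes from the 6 libraries alone, with fewer samples, and 2497 without both KO replicate 3 libraries. Without a low-count filter the WT to KO correlation was 0.44, with genes of few counts added. Replicate blocks gave 2789, 1953, 8740, 8996 and 0 genes (432 unadjusted for the last) in edgeR for the 5 comparisons in the order of the report, and DESeq2 gave 2639, 1904, 8256, 8498 and 0 (235 unadjusted). Culture blocks gave 9292 in WT, 9690 in KO and 0 (688 unadjusted). Total counts gave 875 higher and 1597 lower for KO in DMSO and 573 and 796 in JQ1. Of 11, 10, 11, 11 and 6 called lists, an estimated correlation left 0, 0, 1, 1 and 0. Over all lists fixed beforehand, fry called 2, 4, 17, 16 and 0. Of these fry calls, 2, 3, 11, 11 and 0 were among the lists called by camera with the preset correlation. The shallowest library, WT_JQ1 replicate 3 with 21643592 counts, limits what can be seen in genes of few counts.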

Other observations

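The 7 added lists and the tests on them, on gene span and on expression level were chosen only after the leading genes were seen.

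Deep-layer projection neuron markers fell in KO in DMSO, with 10 of 15 lower and 0 higher and a median log2 change of -0.54, among them Hs3st4 (-0.76) and Nr4a2 (-0.89) besides Sox5, Tle4, Nxph3 and Fezf2. The list had adjusted p = 2.48e-10, and adjusted p = 0.0849 with an estimated correlation. Upper-layer markers had 6 of 12 higher and 0 lower (median 0.24), with Mdga1 (0.59) and Pou3f2 (0.52) higher (adjusted p = 0.001, and adjusted p = 0.15 with an estimated correlation). Of 10 Cajal-Retzius cell markers, Lhx1 (-1.68), Ebf3 (-1.39), Lhx5 (-1.17), Nhlh2 and Trp73 fell and Calb2 (0.56), also an interneuron marker, rose (adjusted p = 0.014, and adjusted p = 0.164 with an estimated correlation). Interneuron markers of caudal origin had 6 of 11 higher and 0 lower (median 0.35), including Cck (0.71) and Htr3a (0.67), and those of medial origin 2 of 11, Maf (0.25) and Kcnc1 (0.21) (median 0.19). Their adjusted p = 0.001 and 0.0265 became adjusted p = 0.15 and 0.208 with an estimated correlation. Genes of all inhibitory neurons had 6 of 8 higher (median 0.47; adjusted p = 7.63e-06, and adjusted p = 0.15 with an estimated correlation). Pan-neuronal markers had 7 of 16 higher, such as Thy1 (0.41), and 2 lower, Dcx (-0.24) and Elavl4 (-0.19) (adjusted p = 0.00354, and adjusted p = 0.15 with an estimated correlation). In JQ1 deep-layer markers fell by a median of 0.47, with 9 lower and 1 higher (adjusted p = 3.87e-09, and adjusted p = 0.112 with an estimated correlation). Without the KO replicate 3 libraries the deep-layer median in DMSO was -0.53 with 10 lower.

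Among the lists that camera did not call in JQ1, p53 target genes had 1 of 20 higher, Sesn2 (0.67), and 10 lower in WT, including the cell death gene Perp (-1.82) and the cell cycle inhibitor gene Cdkn1a (-0.96), and 4 higher and 10 lower in KO (adjusted p = 0.225 and 0.122). Immediate early genes had 6 of 22 higher and 6 lower in WT, with Jun (0.67) higher and Arc (-1.29) and Fosl2 (-0.76) lower. In KO over WT in DMSO 3 of these 22 rose, Egr1, Nr4a1 (0.46) and Egr2 (0.57), and 3 fell, Nr4a2, Fosl2 (-0.40) and Ier5 (-0.26). GABA receptor and inhibitory synapse genes had 3 of 18 higher and 8 lower with JQ1 in WT, with Gabbr1 (0.44) higher and Gabra5 (-0.66) and Gabrg3 (-0.79) lower. Mitochondrially encoded genes did not pass between KO and WT in DMSO (median -0.069, adjusted p = 0.347), and without the KO replicate 3 libraries 5 of 16 fell, with a median of -0.40. Without those libraries the list passed with adjusted p = 1.57e-05, and adjusted p = 0.596 with an estimated correlation (in JQ1 adjusted p = 0.01, and adjusted p = 0.752 with an estimated correlation). These genes varied together (estimated correlation 0.827 in the fit of all libraries).

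The authors' deposited table calls 2822 genes between KO and WT in DMSO, 1534 higher and 1288 lower. Of these, 2015 were also called here, all 2015 with the same sign, and the log2 values correlated over genes with r = 0.816. Fmr1 is listed there at -2 (SE 0.0825) without a p-value, and Mid1 at -1.36 (adjusted p = 7.5e-25), against -3.10 here. The largest absolute log2 value of that table is 2, and how its log2 values were estimated is not stated. They may thus be on another scale than those obtained here, and the gap at Mid1 need not be a disagreement.

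The direction of the JQ1 response varied with expression. In WT 43.2% of the genes in the lowest expression quartile fell and 6.63% rose, and in the highest quartile 14.3% fell and 42.2% rose. By genomic span, 25%, 29.6%, 28% and 35.8% of genes fell in WT from the shortest to the longest quartile. In the same order 23.6%, 26.3%, 30.2% and 24.7% rose, so neither share changed steadily with span. One hypothesis was that longer genes fall more often in JQ1, and Spearman's rank correlation over genes was -0.073 in WT and -0.059 in KO, a weak relation that is consistent with it. Another hypothesis, written after the leading genes were seen, was that deep-layer markers stand apart from expression-matched lists beyond the 4 genes that prompted the list. Without those 4, the other 11 had a median of -0.487, and 0 percent of 10000 matched lists were as low, but 3 of the 11 (Bcl11b, Tbr1 and Nr4a2) had been seen in the lists fixed before, so that value decides nothing. Without these as well, the remaining 8 had a median of -0.38 and 0.01 percent of matched lists were as low (-0.238 and 0.19 percent in JQ1). The matched lists were drawn gene by gene and hold no correlation between genes, so these percents may be too small. In camera with an estimated correlation the whole deep-layer list had adjusted p = 0.0849 in DMSO. That a lower level of deep-layer markers in KO reaches beyond the genes already seen stays a hypothesis, since the 8 were also picked after the result was seen.

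Other splits of the libraries were fitted on the 6 libraries of a comparison alone. The design gives 10 splits, so no share can fall under 0.05. The real split was the 1 with as many calls each time: 2711 against at most 59 in the others for KO and WT in DMSO, 600 against 0 in JQ1, 8802 against 0 for JQ1 in WT and 8126 against 0 for JQ1 in KO, where the 3 other splits that part all pairs also gave 0. For the difference of responses, 30 of 51 regroupings, the real one included, had at least the 355 genes at an unadjusted p under 0.05, and the highest had 6486. Regroupings that mix the genotypes within a treatment carry the genotype effect, a structure of the samples, into this difference, so the count decides nothing about chance.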
